A study of Mus musculus with 9 samples.

How the data were processed

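The samples were 9 single-channel Affymetrix Mouse 430 2.0 arrays hybridised with RNA from wild-type whole spinal cord, wild-type motor neurons and SOD1-mutant motor neurons, 3 arrays each. Groups were taken from the sample descriptions, which name total cord or laser-captured motor neurons and the genotype, and replicate numbers from the titles. The values used were the linear signal intensity of each probe set, as deposited by the authors. The software that computed these intensity values from the scanned images is not given in the sources used here. The values of every array have a trimmed mean of 2500, with 2% of probe sets taken off each end, so the arrays had been scaled to a common level before deposit. Scanner images and detection calls were not used here. Protocols for capture, RNA amplification and labelling are not given in the sources used here.

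Of 45101 probe sets, 64 controls were left out. A pseudocount of 20.3, the 10th percentile of all values, was added before taking log2, so that fold changes of dim probe sets are understated. The authors' scaling was kept. Probe sets whose mean over the 3 group means lay above the 40th percentile were tested, 27022 in all. The platform annotation gave 1 gene for 34945 probe sets, several for 932 and none for 9160, and probe sets with several genes were not named. The 27022 probe sets stood for 12983 genes, each represented by its probe set of highest mean. Symbols were matched to those of the mouse assembly GRCm38.p6, which was used only for names and for the order of genes along chromosomes.

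Each comparison was fitted on its 6 arrays alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, 1 probe set per gene, adjusted over 28 lists, and again with an estimated correlation. There were 30 lists, fixed before the data were examined, with 679 genes, of which 563 were tested. The red blood cell list had too few tested members, and the sex-linked genes were only described. Control transcript ratios were compared with a two-sided exact permutation test, whose smallest p is 0.1 with 3 arrays against 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

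Background was taken per array as the 95th percentile of 27 probe sets for Bacillus subtilis transcripts. Spike-in of such transcripts is not recorded in the labels, and their highest value on any array was 332. Where all arrays of a group lay below it, the change is given as at least N-fold, the mean log2 value of the bright group against the mean over the dim group's arrays of the higher of the background level and the measured value. Where only some arrays were above background, their number is given for the genes described singly.

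The genes named were chosen by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between groups. From each list it took up to 4 passing members with the largest change, or where none passed the 2 of highest mean. It always took Sod1, Chat, Slc18a3, Isl1, Mnx1, Nefl, Gfap, Mbp, Aif1 and Atf3 where measured. Predicted genes and clone names were not named. The members of lists that went against their list (Itm2a, Calb2, Cck), those that passed only when adjusted over the list alone, the 6 probe sets that passed without each array, and all genes first named in the closing observations were chosen after their values were seen. The text describes some of the list members the rule allows.

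The fits were tested on simulated arrays with the real means and spreads, where 200 of 27022 probe sets were changed. For motor neurons against cord, 28.0% of changes of 1 on the log2 scale and 81.0% of changes of 2 were recovered, with 3 false calls. For mutant against wild-type motor neurons, 13.0% and 61.0% were recovered, with 2 false calls. In both, a list shifted by 0.5 was called, and in the fit without that shift no list was. The simulated probe sets varied independently, as real ones do not, so false list calls from correlated genes could not show.

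The alternatives were quantile normalization, centring each array on its median, no filter or a filter at the 60th percentile, a pseudocount 4 times larger or smaller, all 9 arrays in 1 fit, no intensity trend, array weights, the replicate number as a block, and leaving out each array in turn. For lists, the mean of a gene's probe sets, an estimated correlation and fry were also tried. For the control transcripts, Actb in place of Gapdh and the middle probe set in place of the 5′ one were tried. Raising all values to the background level was added after the data were seen.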

Results

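Gene expression was measured on 9 Affymetrix Mouse 430 2.0 arrays, a whole-genome oligonucleotide array on which each transcript is read by 1 or more probe sets. There were 3 arrays of whole spinal cord from wild-type mice. Motor neurons obtained by laser capture microdissection gave 3 arrays from wild-type mice and 3 from SOD1-mutant mice. Laser capture microdissection lifts chosen cells out of a tissue section under the microscope. SOD1 encodes a cytosolic superoxide dismutase, and mutations in it cause an inherited form of amyotrophic lateral sclerosis (ALS), a disease in which motor neurons die. The labels give each sample as from a wild-type or SOD1-mutant mouse but do not name the SOD1 allele, say how the neurons were recognised, or say whether arrays share an animal. The code D28 in every title is not explained, so age and disease stage are not known here. The source field gives ventral spinal cord for every array, while the descriptions call the tissue arrays whole cord. P-values therefore measure the spread between these arrays, which may be partly technical, and 3 arrays per group limit the precision.

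The median signal of an array was 556 to 582 in cord, 269 to 313 in wild-type motor neurons and 274 to 366 in SOD1-mutant motor neurons, with the same trimmed mean of 2500 on all arrays. Over the 27022 probe sets tested, log2 values of 2 cord arrays correlated at 0.976 to 0.983. The correlation was 0.935 to 0.960 between wild-type motor neuron arrays, 0.931 to 0.958 between mutant arrays, and 0.919 to 0.948 between a wild-type and a mutant motor neuron array. A cord array and a wild-type motor neuron array correlated at 0.755 to 0.787. These correlations are across probe sets, which are not independent replicates.

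Captured arrays carried far less signal from the 5′ part of the Gapdh and Actb control transcripts, the 2 in which it was measured. The log2 ratio of 3′ to 5′ signal of the Gapdh control was -0.28 ± 0.01 in cord, 4.03 ± 0.44 in wild-type motor neurons and 4.49 ± 0.15 in mutant motor neurons (SD, n = 3). For the Actb control it was 0.66 ± 0.03, 4.53 ± 0.41 and 5.28 ± 0.59 in the same order (SD, n = 3). Between wild-type motor neurons and cord, the Gapdh ratio differed by 4.31 and every captured array lay above every cord array (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 allows). Between mutant and wild-type motor neurons, it differed by 0.46 (exact p = 0.2) for Gapdh and by 0.75 (exact p = 0.2) for Actb.

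**Figure D1:**
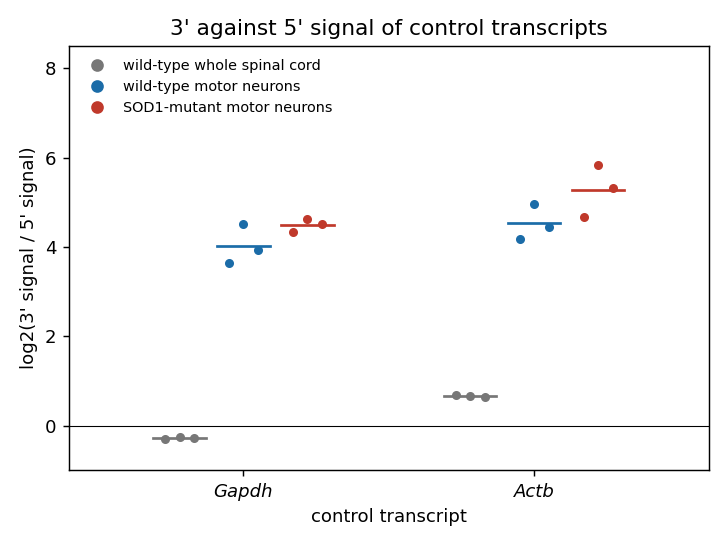
Log2 ratio of 3′ to 5′ signal (y axis, no unit) of the Gapdh and Actb control transcripts (x axis), 1 point per array and a line at each group's mean (n = 3). The cord arrays sit near 0 and the captured arrays of both genotypes between 3.65 and 5.84.

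The first comparison set wild-type motor neurons against wild-type whole cord. Its differences mix the content of the captured cells with the loss of 5′ signal on their arrays, and the 2 were not separated. In this comparison the Gapdh control had a log2 change of 0.55 at its 3′ probe set and -3.76 at its 5′ one. For the Actb control these were -0.43 and -4.29. Motor neuron genes were much higher in the captured cells. Mnx1, a transcription factor of motor neuron identity, was 22.5-fold higher (log2 fold change 4.49 ± 0.17, SE, adjusted p = 2.54e-07), and Isl1, another such factor, 12.5-fold (3.64 ± 0.30, adjusted p = 1.00e-05). Slc18a3, the vesicular acetylcholine transporter, was 4.08-fold higher (2.03 ± 0.11, adjusted p = 1.24e-06). Glial, microglial, vascular and interneuron genes were lower, among them the astrocyte filament gene Gfap (15.1-fold, log2 fold change -3.91 ± 0.26) and the GABA-synthesising enzyme gene Gad1 (24.9-fold, -4.64 ± 0.21).

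With limma, 17700 of 27022 probe sets passed an adjusted p of 0.05, 6494 higher and 11206 lower in motor neurons. The median log2 change of all probe sets tested was -0.35. It became 0.38 after centring each array on its median and 0.13 after quantile normalization. The split followed: 11695 higher and 6248 lower after centring, and 9654 higher and 7685 lower after quantile normalization. In all 3 scalings, 11831 probe sets passed in 1 direction, 5996 higher and 5835 lower. Of 3722 genes with 2 or more called probe sets, 1291 had calls in both directions, so that a change read from 1 probe set need not hold for the whole transcript.

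**Figure D2:**
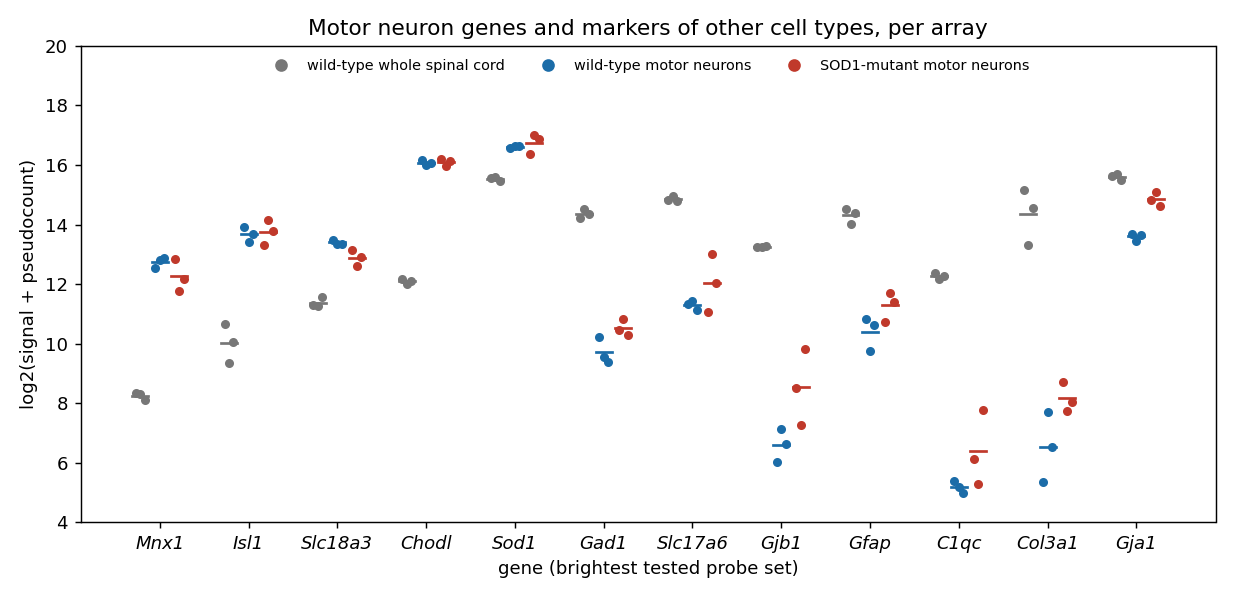
Log2(signal + pseudocount) of 12 genes (x axis) on each array, 1 point per array and a line at each group's mean (n = 3). Mnx1, Isl1, Slc18a3, Chodl and Sod1 lie higher in both captured groups than in cord, and Gad1, Slc17a6, Gjb1, Gfap, C1qc, Col3a1 and Gja1 lower.

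Among the motor neuron and cholinergic genes, 14 of 17 tested rose and none fell, with a median log2 change of 2.40 (camera adjusted p = 1.09e-06, and adjusted p = 0.090 with an estimated correlation). Beside Mnx1, the largest rises were those of Calcb, which encodes a calcitonin gene-related peptide (16.4-fold), Chodl, a marker of fast motor neurons (15.8-fold), and the matrix metalloproteinase gene Mmp9 (15.1-fold). Chat, the acetylcholine-synthesising enzyme, was read by 1 dim probe set and did not pass with the authors' scaling (log2 fold change 0.61 ± 0.28, adjusted p = 0.082), but rose after centring (1.34, adjusted p = 0.00249) and after quantile normalization (1.43, adjusted p = 0.00173). Atf3 was measured but fell below the filter on dim probe sets. Sod1 itself rose 2.11-fold (1.07 ± 0.07, adjusted p = 1.89e-06), and Nefl, the neurofilament light chain, 1.73-fold (0.79 ± 0.07, adjusted p = 2.21e-05).

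By measured log2 change on each gene's brightest probe set, the 10 genes with the largest rise were Ttr, Kcnj14, Pde6b, Polr1c, Cd7, Spp2, Mnx1, Gnmt, Rasl10a and Tph2. This ranking also uses values below background, so its order is not certain. Kcnj14, an inward rectifier potassium channel, went from a mean signal of 1838 in cord to 48880 in motor neurons (26.5-fold, log2 fold change 4.73 ± 0.12, adjusted p = 8.12e-08). Polr1c, a subunit shared by RNA polymerases, was 24.3-fold higher, but only 1 of its 2 tested probe sets was called. Ttr (transthyretin, a thyroid hormone carrier), Pde6b (a phosphodiesterase subunit of rod photoreceptors), Spp2, Rasl10a and Tph2 (the neuronal enzyme of serotonin synthesis) lay below background on all 3 cord arrays and were at least 14.7-fold, 10-fold, 9.41-fold, 12.2-fold and 6.84-fold higher. Cd7 and Gnmt, above background on 1 cord array each, were 23.2-fold and 18.2-fold higher.

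Ranked in the same way, with values below background included, the 10 with the largest fall were Serpinb1b, Bex1, Col3a1, Igf2, Tac2, C1qc, Ahnak, Pmp2, Zic1 and Ogn. Of these, 6 lay below background on all 3 wild-type motor neuron arrays: Bex1 was at least 142-fold lower, the growth factor gene Igf2 at least 105-fold, the protease inhibitor gene Serpinb1b at least 74.6-fold, the tachykinin gene Tac2 at least 52.8-fold, the myelin protein gene Pmp2 at least 43.9-fold and the complement gene C1qc at least 30.9-fold. Col3a1, a fibrillar collagen of meninges and vessels, was 225-fold lower (log2 fold change -7.81 ± 0.61, adjusted p = 8.10e-06). Ahnak, the transcription factor gene Zic1 and the proteoglycan gene Ogn were 134-fold, 123-fold and 113-fold lower. Col3a1 and these 3 genes were above background on 1 motor neuron array.

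Markers of other cell types fell as groups. All 18 oligodendrocyte and myelin genes tested fell (median log2 change -2.43, camera adjusted p = 5.49e-09), as did all 17 microglia and macrophage genes (-3.19, 1.19e-06), and both lists had an adjusted p = 0.113 with an estimated correlation. The astrocyte list had 16 of 19 genes lower (-2.93, 8.59e-06), the vascular and meningeal list 17 of 18 (-2.56, 3.98e-05), and the Schwann cell and peripheral nerve list 5 of 6 (-2.54, 0.0185). In the same order, adjusted p = 0.313, 0.141 and 0.291 with an estimated correlation. After centring, 16 oligodendrocyte genes were lower and 1 higher, with 15 and 3 for astrocytes, 16 and 1 for vessels and meninges, and 5 and 1 for Schwann cells. After quantile normalization, the numbers lower were 18, 19, 15 and 6 in the same order, and none was higher. The 17 microglial genes stayed lower in both, and these lists all stayed called. The exception in the vascular list was Itm2a, higher by a log2 change of 0.72 on its brightest probe set and lower on its other, and the rise was lost after quantile normalization (adjusted p = 0.0791). Gjb1, a myelin connexin, was at least 61.2-fold lower. Fa2h, a sphingolipid enzyme of myelin, was 16.5-fold lower. Agt (39.3-fold) and the water channel gene Aqp4 (10.6-fold) stood for astrocytes, P2ry12 (27.1-fold) for microglia, with 2 of 3 motor neuron arrays above background, and Col1a2 (77.8-fold) for meninges and vessels. Aif1, a microglial gene, was at least 6.94-fold lower.

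The brightest probe set of Mbp, the main myelin protein gene, had a mean signal of 144200 in cord and 115200 in wild-type motor neurons (log2 fold change -0.32 ± 0.08, adjusted p = 0.00742), and it turned to 0.40 after centring. On cord replicate 3 it was the brightest probe set of the array, and saturation was not tested. Of its 8 tested probe sets, 4 fell and none rose, and 1 of them went from 128200 to 174900 in cord to 1015 to 1421 in wild-type motor neurons. The 3 probe sets of Gfap also differed in size: 2 of them, at 51910 to 62220 in cord, were at 270 to 472 in wild-type motor neurons.

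Markers of other neuron classes were lower too. Of 11 inhibitory interneuron markers, 10 fell and 1, the calcium-binding protein gene Calb2, rose by a log2 change of 1.32 (list median -3.69, camera adjusted p = 0.00266, and adjusted p = 0.141 with an estimated correlation). The neuropeptide gene Sst fell 48.5-fold, Gad2 27.7-fold, with 2 of 3 motor neuron arrays above background, and the calcium buffer gene Calb1 26.3-fold. Of 13 excitatory and dorsal horn markers, 9 fell and 1, Cck, rose by a log2 change of 1.39 (median -2.32, camera adjusted p = 0.01, and adjusted p = 0.291 with an estimated correlation). After centring, 7 inhibitory markers were lower and 1 higher, and 7 excitatory ones lower and 2 higher. After quantile normalization, the counts were 9 and 1 for inhibitory and 7 and 1 for excitatory markers. Slc17a6, the vesicular glutamate transporter, fell 11.7-fold, the transcription factor gene Ebf2 at least 16.6-fold, and Tac1, a tachykinin above background on 2 of 3 motor neuron arrays, 72.2-fold.

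Genes of oxidative phosphorylation and glycolysis, chaperones and proteasome subunits were higher in motor neurons as lists, on the same arrays that had lost 5′ signal. Of 51 genes of oxidative phosphorylation, 42 rose and 3 fell (median 0.77, camera adjusted p = 2.81e-09, and adjusted p = 0.313 with an estimated correlation). After quantile normalization, 32 of them rose and 10 fell (median 0.29, adjusted p = 0.0379). The subunits of the first respiratory complex Ndufa5 (4.07-fold), Ndufb3 (3.53-fold), Ndufa2 (3.23-fold) and Ndufs7 (3.01-fold) led. Of 27 cytosolic and mitochondrial chaperones, 24 rose and none fell (median 1.09, camera adjusted p = 8.90e-09, and adjusted p = 0.0658 with an estimated correlation), with Bag3 at 10.7-fold, Hspb8 at 8.65-fold, Hspb1 at 4.49-fold and Chordc1 at 4.46-fold. Hspb8 had 1 of its 3 probe sets called higher and 1 lower. Of 31 proteasome subunits, 26 rose and 4 fell (median 1.06, camera adjusted p = 4.93e-07, and adjusted p = 0.113 with an estimated correlation). Psmb3 rose 5.94-fold and Psmd7 fell 4.63-fold. Of 12 glycolysis genes, 9 rose and 1 fell (median 0.67, camera adjusted p = 0.00376, and adjusted p = 0.313 with an estimated correlation), led by Pfkp (2.52-fold on its brightest probe set, with 2 others called lower) and the lactate dehydrogenase gene Ldha (2.33-fold). The glycolysis call was lost after quantile normalization (median 0.21, adjusted p = 0.547).

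In the remaining lists camera made no call with the authors' scaling, and in most of them members went both ways. Other scalings gave calls for 4 of them: after quantile normalization, cholesterol and lipid synthesis (adjusted p = 4.52e-05), ribosomal proteins (7.79e-05) and synaptic release (0.0293) were lower, and after centring, complement, interferon and antigen presentation was lower (0.0355). Of 20 neurofilament and axonal cytoskeleton genes, 12 rose and 5 fell (15 and 4 after centring, 9 and 7 after quantile normalization). Tubb3, the neuronal beta tubulin, rose 4.85-fold and Sncg, a synuclein, 5.65-fold, while Tubb4a fell 9.43-fold and the growth cone gene Gap43 6.67-fold. Synaptic release genes split into 9 higher and 10 lower of 21, with Sv2b 4.66-fold higher and Syt1 11.3-fold lower. Neuronal ion channels and pumps had 7 higher and 8 lower of 21, and Kcnc2, a fast potassium channel, fell 17.5-fold. Of 18 glutamate receptor genes, 3 rose and 10 fell. Grin3b, an NMDA receptor subunit, rose 8.24-fold and Grm5, a metabotropic receptor, fell 36.7-fold. Axonal transport genes had 11 higher and 9 lower of 25, the dynactin subunit Dctn3 at 3.35-fold higher and the kinesin Kif1a at 4.91-fold lower. Antioxidant genes had 13 higher and 7 lower of 24, with mitochondrial Sod2 4.21-fold higher on its brightest probe set, 2 of its 4 probe sets higher and 2 lower. The extracellular enzyme gene Sod3 was 15.5-fold lower and above background on 1 motor neuron array.

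Counts for the other lists were 6 higher and 12 lower of 24 for endoplasmic reticulum stress, 13 and 7 of 21 for autophagy and lysosome, 9 and 8 of 21 for the axon injury response, and 6 and 11 of 21 for apoptosis. They were 3 and 8 of 16 for complement, interferon and antigen presentation, 0 and 5 of 12 for cytokines, and 10 and 7 of 19 for genes linked to inherited ALS or motor neuron disease. Immediate early genes had 3 higher and 7 lower of 15, cytosolic ribosomal proteins 9 and 8 of 28, and cholesterol and lipid synthesis 3 and 11 of 18. These counts moved with the scaling: after centring, endoplasmic reticulum stress had 14 higher and 4 lower, autophagy and lysosome 15 and 1, ribosomal proteins 20 and 4, axonal transport 17 and 2, glutamate receptors 6 and 7, synaptic release 13 and 8, apoptosis 8 and 2, cholesterol and lipid synthesis 9 and 5, ion channels and pumps 11 and 8, cytokines 4 and 3, inherited ALS genes 14 and 4, and immediate early genes 5 and 4. After quantile normalization autophagy and lysosome had 8 higher and 7 lower, ribosomal proteins 3 and 16, axonal transport 9 and 13, glutamate receptors 6 and 7, and synaptic release 6 and 11. Apoptosis then had 8 and 4, cholesterol and lipid synthesis 1 and 13, ion channels and pumps 9 and 11, cytokines 2 and 5, inherited ALS genes 7 and 8, and immediate early genes 5 and 4. Of the 2 red blood cell markers tested, too few for a list test, Fech rose 1.25-fold, which was lost after quantile normalization (adjusted p = 0.0559). Adjusted over the list alone, the counts were the same except 5 lower for oxidative phosphorylation, 1 lower for chaperones and 4 higher for cholesterol and lipid synthesis. These 3 lists and all others were fixed before the data were examined. With an estimated correlation, no list was called.

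The second comparison set SOD1-mutant against wild-type motor neurons and shows how signal on the captured arrays differed between the genotypes. Few genes passed. Among the rises that passed whichever array was left out were those of Tmem87a, a membrane protein of the secretory pathway (22.5-fold, log2 fold change 4.49 ± 0.24, adjusted p = 4.82e-05), Nudt19, a hydrolase of the Nudix family (5.33-fold on 1 probe set, 2.41 ± 0.16, adjusted p = 0.000129, with its other probe set at 0.33 and not called), and Chchd4, which imports proteins into the mitochondrial intermembrane space (5.15-fold, 2.36 ± 0.17, adjusted p = 0.000229). Bex1, a small neuronal signalling adaptor, went from below background on all 3 wild-type arrays to a mean signal of 4292 in mutant arrays (at least 17.2-fold, adjusted p = 0.0358), against 22590 in whole cord. Its mutant arrays varied widely (SD 1.94 on the log2 scale), and of the 6 fits that left out 1 array it passed only in that without mutant replicate 1, with log2 changes from 4.31 (without mutant replicate 2) to 6.18 (without mutant replicate 1). Motor neuron identity genes and Sod1 itself did not pass.

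With limma, 60 probe sets passed an adjusted p of 0.05, 41 higher and 19 lower in mutant motor neurons. At an unadjusted p of 0.05 there were 4117, where chance alone would give 1351 on average. Probe sets are not independent, so the number by chance can lie far from that mean, and its spread was not measured. The share of higher calls, 68.3%, became 83.3% after quantile normalization, with 30 higher and 6 lower. The directions were nearly even in the 3 fits with the most calls (572 higher and 612 lower with all 9 arrays, 226 and 217 with the replicate block, and 6250 and 7527 with array weights) and at an unadjusted p (1921 and 2196). These 3 fits carry limits. Cord arrays were expected to be less noisy and to make the shared spread of the 9-array fit too small. The limits of the block and the weights are given below. The number moved when an array was left out: it was 6 without wild-type replicate 3, 7 without mutant replicate 3, 11 without wild-type replicate 1 and 13 without wild-type replicate 2. No probe set was called lower in any of these fits. The number was 46 without mutant replicate 1 (28 higher and 18 lower) and 71 without mutant replicate 2 (45 and 26). All fits that left out 1 array have the same number of arrays, so their size alone does not account for this range. Its cause was not tested. The number was 3 without the intensity trend and 1184 when all 9 arrays were fitted together. Without any 1 of the 6 captured arrays, 6 probe sets remained past the test, those of Tmem87a, Nudt19 and Chchd4, 1 probe set each of Rps9 and Hspa13, and 1 for which no gene was named.

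**Figure D3:**
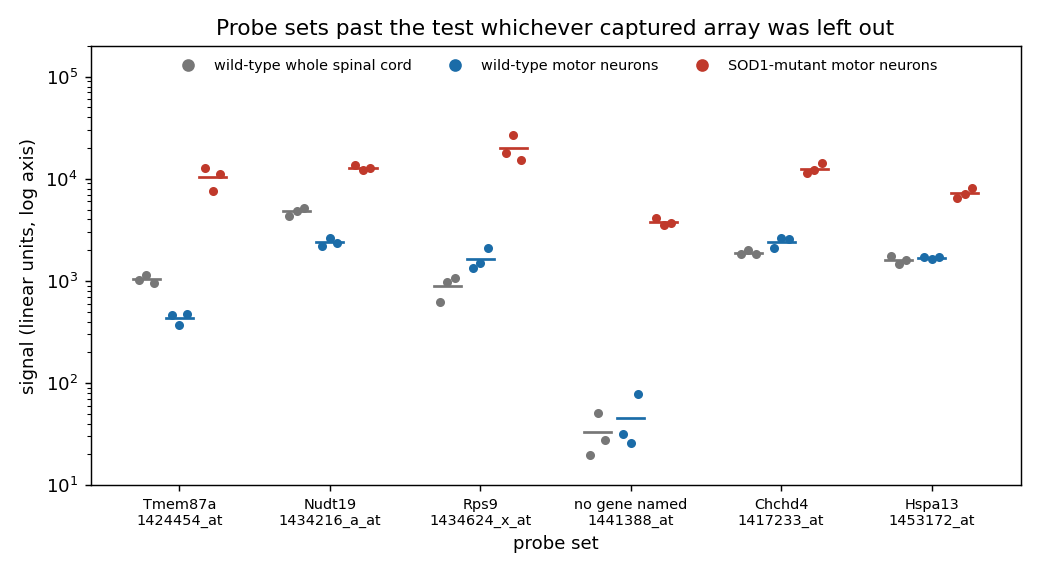
Signal (linear units on a log axis) of the 6 probe sets that passed the test of mutant against wild-type motor neurons whichever of the 6 captured arrays was left out, 1 point per array and a line at each group's mean (n = 3). In each, the 3 mutant arrays lie above all 6 wild-type arrays, cord and motor neurons alike.

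With each gene read by its brightest probe set, the 10 genes with the largest rise in mutant motor neurons were Bex1, Kcnj9, Tmem87a, Fam227b, Nudt19, Chchd4, Slc15a2, Susd5, Enc1 and Sdc4. Kcnj9, an inward rectifier potassium channel subunit, had a mean signal of 66.3 in wild-type and 1831 in mutant motor neurons (28-fold, adjusted p = 0.0176). It was above background on 1 of the 3 wild-type arrays, and its 2 other tested probe sets were not called. The peptide transporter gene Slc15a2 (4-fold), the actin-binding protein gene Enc1 (3.90-fold) and the proteoglycan gene Sdc4 (3.88-fold) were higher in mutant motor neurons but lay below their level in cord. The 2 other probe sets of Slc15a2 had a median log2 change of -1.47, and the other probe sets of Sdc4 and Enc1 had -0.14 and 1.01, none of them called. Fam227b and Susd5 were 5.86-fold and 3.96-fold higher. Slc15a2 (adjusted p = 0.0624) and Susd5 (adjusted p = 0.0528) did not pass after quantile normalization, nor in any of the 6 fits that left out 1 array. Of those 6 fits, Kcnj9 and Fam227b passed in 3 each, and Enc1 and Sdc4 in 1 each. The adjusted p of these genes other than Tmem87a, Nudt19 and Chchd4 lay between 0.0170 and 0.0485.

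On each gene's brightest probe set, the 10 with the largest fall were Rec8, H2bc18, Lcmt2, Tsc2, Ing5, Prim1, Sbsn, Mtfmt, Ramp2 and Fibp. None of them passed in more than 2 of the 6 fits that left out 1 array, and Tsc2 and Mtfmt passed in none. Rec8, a meiotic cohesin, and the histone gene H2bc18 were 4.67-fold (adjusted p = 0.0282) and 4.64-fold (adjusted p = 0.0317) lower. Tsc2, which encodes tuberin, an inhibitor of mTOR signalling, was 3.07-fold lower (adjusted p = 0.0485). The methyltransferase gene Lcmt2 was 3.19-fold lower (adjusted p = 0.0358), and Prim1, the DNA primase subunit, 2.55-fold (adjusted p = 0.0385). Ramp2 (adjusted p = 0.0474) and Fibp (adjusted p = 0.0387) fell less. After quantile normalization only Rec8 and H2bc18 of these 10 still passed, the others having an adjusted p of 0.0528 to 0.0682. The other probe sets of Prim1, Sbsn, Mtfmt and Fibp had median log2 changes of -0.48, -0.48, 0.13 and 0.09, none of them called.

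Sod1 had a mean signal of 99910 in wild-type and 112300 in mutant motor neurons (log2 fold change 0.14 ± 0.16, adjusted p = 0.698). The probes read the mouse transcript, and the labels do not say what the mutation is, so this value does not check the genotype. Mnx1 (-0.48 ± 0.25), Isl1 (0.08 ± 0.21), Slc18a3 (-0.52 ± 0.17), Chat (-0.11 ± 0.41) and Nefl (0.07 ± 0.14) did not pass. Nor did Gfap (0.88 ± 0.33), Mbp (0.31 ± 0.11) and Aif1 (0.23 ± 0.92), each given as log2 fold change ± SE.

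Of the 28 lists, camera called 2 with the authors' scaling. Astrocyte markers were higher in mutant motor neurons (median log2 change 0.38, adjusted p = 9.72e-05, and adjusted p = 0.699 with an estimated correlation). Gja1, the main astrocyte connexin, was the 1 member of 19 that passed (2.38-fold, log2 fold change 1.25 ± 0.15, adjusted p = 0.0170), with a mean signal of 12470 in wild-type motor neurons, 29860 in mutant motor neurons and 49780 in cord. Gja1 passed in 2 of the 6 fits that left out 1 array, with log2 changes from 1.12 to 1.36. Adjusted over the list alone, 5 of 19 astrocyte markers were higher. Proteasome subunits were lower (median -0.17, camera adjusted p = 0.0375, and adjusted p = 0.699 with an estimated correlation), no single subunit of 31 passed (the brightest, Psmb3 and Psma6, had log2 changes of 0.02 ± 0.15 and 0.12 ± 0.11), and the call was lost after centring (adjusted p = 0.0968) and kept after quantile normalization (0.000416). Quantile normalization also called glycolysis lower (median -0.19, camera adjusted p = 0.00215). With the authors' scaling its camera adjusted p was 0.209, and 0.699 with an estimated correlation. The 3′ to 5′ ratio of Gapdh was higher by 0.46 on the same mutant arrays.

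**Figure D4:**
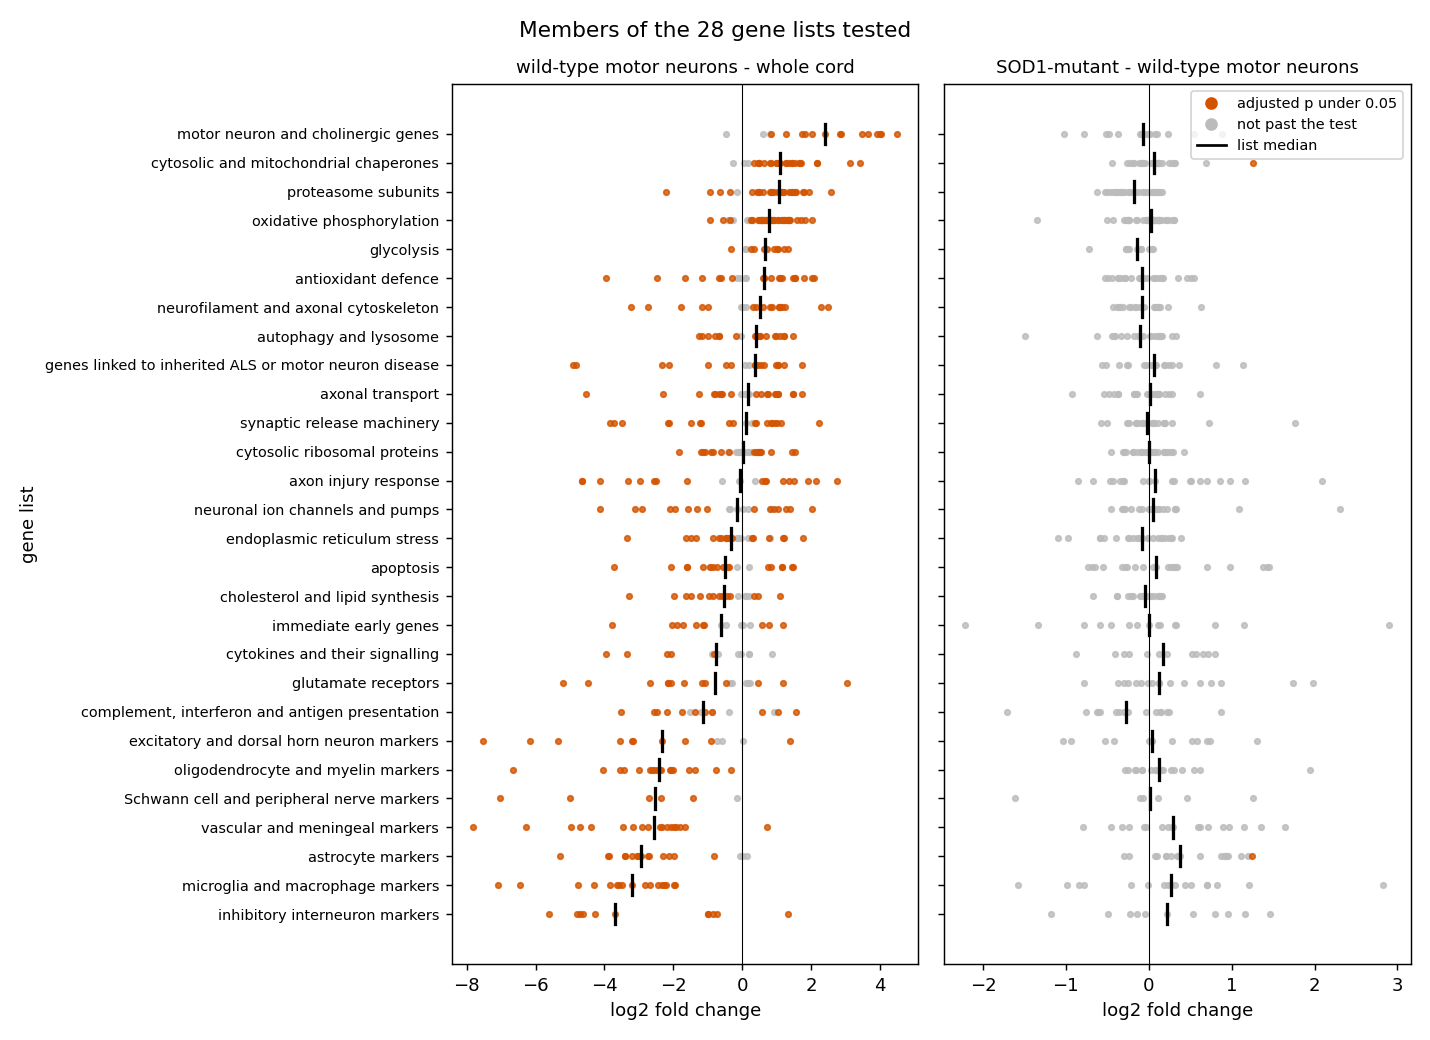
Log2 fold change (x axis) of each tested member of the 28 gene lists (y axis), for wild-type motor neurons against cord (left) and mutant against wild-type motor neurons (right). Points past an adjusted p of 0.05 are orange and others grey, with a black line at each list's median. Members pass throughout the left panel, and on the right only Gja1 and Hspa1b do.

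Among the other lists 1 gene passed, the inducible heat shock protein gene Hspa1b (2.39-fold, log2 fold change 1.26 ± 0.18, adjusted p = 0.0317), with 2 of its 3 probe sets higher. Hspa1b passed in 1 of the 6 fits that left out 1 array, with log2 changes from 1.175 to 1.404. It was 1 of 27 chaperones tested, and the median of that list was 0.06. The 17 motor neuron and cholinergic genes had a median of -0.06 and none passed. Adjusted over the list alone, 2 were higher and 4 lower. None of the 20 neurofilament and axonal cytoskeleton genes (median -0.08), 25 axonal transport genes (0.01), 24 endoplasmic reticulum stress genes (-0.08), 21 apoptosis genes (0.08) or 21 axon injury genes (0.07) passed. The same was true of the 51 genes of oxidative phosphorylation (0.03), 18 vascular and meningeal genes (0.29, 12 of them above 0), 17 microglial genes (0.26), 11 inhibitory interneuron genes (0.22), 18 oligodendrocyte genes (0.12) and 19 genes linked to inherited ALS or motor neuron disease (0.06). Adjusted over the list alone, 3 immediate early genes were higher and 3 lower, 2 ion channel genes (Kcnc2 and Cacna2d1) and 2 cytokine signalling genes (Il6st and Nfkbia) were higher, and 2 endoplasmic reticulum stress genes (Pdia3 and Manf) were lower. Adjusted in the same way, Grm5 and Bcl2l11 were higher, and Tnfrsf1a, Cox7c, Rab3c, Calb2, Ncmap and Tapbp were lower, each the only member of its list in that direction.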

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

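Of the alternatives, only the values raised to the background level were chosen after the data and first results were seen. In motor neurons against whole cord, the number of probe sets changed stayed within 1.5 times of 17700 in every alternative, and the directions moved with the scaling as described above. Mbp turned to 0.40 after centring. The ribosomal protein list, with a median of 0.01, turned to -0.36 after quantile normalization. With fry, this list (fry adjusted p = 0.0445) and the inherited ALS list (fry adjusted p = 0.0192) were lower, opposite to camera's direction. Their medians were 0.00628 and 0.36 and their means -0.0644 and -0.386, and the cause was not tested. The 12 lists became 0 with an estimated correlation and 28 with fry, which does not compare a list with other genes. Leaving out 1 array gave 15477 to 18336 probe sets and 12 to 12 lists. The 3′ over middle ratio of Gapdh differed by 1.56 where the 3′ over 5′ ratio differed by 4.31.

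In mutant against wild-type motor neurons, the 60 probe sets became 36 with quantile normalization, 1184 with all 9 arrays in 1 fit and 3 without the intensity trend. They became 95 with values raised to the background level. Array weights gave 13777, with weights of 10.8 for wild-type replicate 3 and 5.47 for mutant replicate 3 against 0.281 to 0.429 for the others, so that the fit rested on 1 array per group. The replicate block gave 443 (17333 in motor neurons against cord), but the numbers share only a number: deviations of same-numbered arrays correlated at 0.145, 0.171 and 0.002 (0.031, 0.005 and -0.003 in motor neurons against cord), and not every array correlated best with its own number. Leaving out 1 array gave 6 (without wild-type replicate 3) to 71 (without mutant replicate 2) probe sets and 1 to 2 lists. The 2 lists became 0 with an estimated correlation, 0 with fry, and 1 with centring, with the filter at the 60th percentile and with array weights. Where no cause is named, the cause was not tested.

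Over the planned and added settings, single named genes kept their side of the threshold, and their direction where they passed, in 2232 cases. They fell short of the threshold in 19 cases, both counts for motor neurons against cord. In mutant against wild-type motor neurons, the counts were 1225 and 125. Genes that passed in neither fit count as kept even where their sign changed, so these counts do not give the share of calls lost. Of the genes that the rule named in mutant against wild-type motor neurons, few held. Only Tmem87a, Nudt19 and Chchd4 passed in all 6 fits that left out 1 array. In that comparison Nefl, with a log2 change of 0.0672, turned to -0.00748 after quantile normalization and passed in neither fit. Signals under the background controls (131 to 244 per array) limit what dim genes can show.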

Other observations

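The tests of scaling, tissue, RNA length and single probe sets, the splits for probe sets in motor neurons against whole cord, and the longest run of neighbouring genes were chosen after the results they measure were seen, and those of tissue and RNA length were also revised after their own first outcome.

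Of the 6 tested probe sets of Gja1, 2 were called higher in mutant motor neurons, and other genes varied in how far their probe sets moved together. A probe set of the astrocyte glutamate transporter gene Slc1a2 was higher (log2 fold change 1.85), while the median of its 2 other tested probe sets was -0.27. A probe set of Marcks, a membrane-bound actin regulator, was higher by 1.36, with a median of 1.24 over its 5 others, and 1 of Fkbp9 by 1.87, with 1.75 for the other. All 9 arrays had high signal from Xist (12560 to 44600 for its brightest probe set), and no probe set of the Y-linked genes Eif2s3y, Kdm5d and Uty exceeded 335.

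Of 41 probe sets higher in mutant motor neurons, 30 (73.2%) were called lower in wild-type motor neurons than in cord, against 41.5% of all probe sets, and 17.0 would be expected from independent lists. Both comparisons use the same wild-type motor neuron arrays, and these 3 are too few to split. In 100 simulated draws with no mutant effect, probe sets varied independently, as real ones do not. The median share was 58.5% and the highest 78.0%, and 5 draws reached the observed share, so the shared wild-type motor neuron arrays may account for that share. Over all 27022 probe sets, the covariance of the log2 changes of both comparisons was -0.182, against a simulated mean of -0.104 and a lowest of -0.117. That lay beyond every draw, but independent draws understate how far it can vary, so whether the shared arrays suffice is not settled.

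The higher astrocyte markers in mutant motor neurons hardly moved with the scaling, which argues against the authors' scaling as the cause. After quantile normalization their median was 0.38 and the list was called (camera adjusted p = 0.000232). It was also called after centring, but that shifts all changes of a comparison alike and so adds little. Shorter RNAs cannot be told apart: the 13 astrocyte probe sets that had lost more signal than a sibling in captured cells come from only 7 genes, and their median mutant change over genes was 0.286 ± 0.171 (robust SE) where a fall was predicted, in a test whose choice of probe sets, unit and bound were all revised after results were seen. More tissue captured with the mutant neurons stays open: as a share of the cord level, astrocyte markers gained a median of 5.64% and other non-neuronal markers 1.83% (permutation p = 0.00469 over genes, which are not independent). A comparison per array was added after that p had argued against tissue, and the astrocyte excess was 16.2, -0.152 and 6.50 percentage points in mutant replicates 1 to 3 and 3.48, -3.43 and -3.32 in wild-type ones, so the groups overlapped. The call itself is weak, because it was lost with an estimated correlation (camera adjusted p = 0.699). The list also passed in 5 of the 10 splits of the 6 arrays, the real one included, at a camera adjusted p as low as 4.06e-05 against 9.72e-05. The other splits keep part of any mutant difference, so they cannot measure how weak the call is. An effect of the SOD1 genotype on astrocytes or neurons was not tested.

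The 6 probe sets that passed without each array stood above both wild-type groups, and only 3 of them belong to a gene with another tested probe set, which in none of the 3 followed. For Nudt19, Rps9 and Hspa13, log2 changes of 2.41, 3.57 and 2.08 stood against medians of 0.33, -0.05 and 0.23 for the other probe sets, and the probe set without a named gene was at least 23.8-fold higher. In 71.9% of the 32 genes with a called and another tested probe set, the median of the others was under 50% of the change in the called direction. Moves the other way count among these. Sequence or splice differences under single probe sets would give this, but how often the choice of extreme probe sets alone gives it was not measured. Called genes had 6 neighbouring pairs within 20 tested genes on a chromosome, against a median of 3 in 100000 random draws (permutation p = 0.103). That count takes pairs from anywhere in the genome, so it cannot decide on 1 chromosomal segment inherited with the mutation. The longest run held 4 genes, Ndufaf1, Tmem87a, Lcmt2 and Ppip5k1 (permutation p = 0.014). The pairs outside it were Kcnj9 with Kcnj10, Tsc2 with Tmem204, and Hddc3 with Homer2. A difference in genetic background between the mice may deserve a test with sequence data.

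Splits of the 6 arrays into groups of 3 number 10, too few for a share under 0.05. Every other split mixes arrays of both groups, so it keeps part of any difference and adds the rest to the spread within groups. That favours few probe set calls while lists can still be called, so the other splits are no reference without a difference. For motor neurons against whole cord, the real split gave 17700 probe sets and the highest other 0, and it gave 12 lists, as did the highest other at 12. For mutant against wild-type motor neurons, it gave 60 probe sets and the highest other 0, and it gave 2 lists and the highest other 4. Of the 10 splits, 1 gave as many probe sets in each comparison, 2 as many lists in the first and 6 in the second.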
